A study of Mus musculus with 2 samples.

How the data were processed

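Total RNA of mouse CD8 T cells was measured on Affymetrix microarrays, on 1 array of Tc1 cells and 1 array of Tc9 cells, both at day 5 of culture. The title and the description of the second sample name it Tc9, while its source name calls it Tc1. It was treated as Tc9, from its title.

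The deposited table holds probe set intensities on a linear scale, made by the authors from the scanned arrays. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin by a sense-target whole-transcript method. The summarization of probes into probe sets, the background correction and the normalization are not given in the sources used here. Over all probe sets, the values ran from 5.12 to 14977 on the Tc1 array and from 4.87 to 13045.4 on the Tc9 array. The quantiles of both arrays lay close together, with medians of 57.2 and 53.1 and upper quartiles of 330.5 and 346.2, so the values were taken as already normalized between arrays. The analysis written before the data were examined called for log2 and quantile normalization unless the deposited values were normalized log2 values. They were linear, and whether they were normalized is inferred from their quantiles. The main values are log2 of the deposited intensities without further normalization, which departs from that wording, and the quantile normalized values are given beside them among the alternatives.

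The table lists 28846 probe sets. Of these, 19572 have 1 gene symbol in the platform annotation used here, none has several and 9274 have none, most of which are control probe sets. All 19572 Entrez gene numbers matched the GRCm38.p6 RefSeq gene table, which changed no symbol. This gave 19505 genes. For the 55 genes with several probe sets, the probe set with the higher mean log2 signal was used. No genome build is named for the array, so no coordinates are given.

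The deposited table gives no detection calls. A gene was called detectable where its brighter array reached the median of all gene values on both arrays, a log2 signal of 6.43, and 10147 genes (52.0%) did so. Of the 5222 control probe sets whose IDs carry the word neg, 89.9% lay below this threshold on the Tc1 array and 91.7% on the Tc9 array. The background probe sets, which are named by GC content, reached 8.53 on the Tc1 array and 8.65 on the Tc9 array, so the threshold is not a background level for every probe. Where a gene lay below the threshold on 1 array, its fold is given as "at least", computed with the threshold in place of the dim value, and the order among such genes has no meaning. Counts of genes past 2-fold and list medians use the measured values, and each list median that differs at 2 decimals with dim values at the threshold is given so in the closing section, the larger changes also beside the list. No fold is given for a gene below the threshold on both arrays. Gene families with near-identical members, such as Gbp, Ly6c, Ifi200, Ms4a4, Chil and granzyme genes, can share probes, and their members may not be separated.

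Differences are log2 Tc9 minus log2 Tc1. With 1 array per group there is no replicate check, and no p-value or standard error is given. A size rule of 2-fold describes these 2 arrays, not the conditions. The number of arrays limits the precision. Genes were named by a rule written before these values were seen. It took the 12 detectable genes with the largest and the 12 with the smallest measured difference, leaving out predicted, microRNA and receptor segment genes. It added 11 identity genes whatever their value, and up to 4 detectable members of each gene list. Other genes were named after their values were seen: the remaining members of a list where 5 or fewer passed 2-fold, Il4, Il5, Il13, Mx1, Rtp4, 5 inhibitory receptor genes, the genes that enter either set of 12 with dim values at the threshold, and the genes of the closing observations outside the lists. Of the genes past 2-fold, 4 higher and 16 lower ones were predicted, microRNA or receptor segment genes and were only counted. The 29 gene program lists and 11 lists of markers of other cell types were written at the same time. They held 620 genes in the program lists, of which 566 had a probe set. For each list the median difference of its measured genes was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. These percentiles describe the 2 arrays, and genes are not replicates.

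The count rule and the list percentile were tested on simulated data for Tc9 against Tc1, over 19505 genes. Of 100 detectable genes changed by 1.5 on the log2 scale, 87% were recovered, and of 100 changed by 2.5, 100% were. Of 9947 unchanged detectable genes, 0.553% passed 2-fold. Of 100 unchanged lists, 4% fell outside the central 95% of random lists. The simulated noise was normal, independent between genes and of the same spread at all intensities. Its size was the robust spread of the Tc9 minus Tc1 differences of these same arrays. The 87%, 100% and 0.553% therefore depend on that choice and measure no error between replicates. On the real arrays, 16.2% of the 585 control probe sets with neg in their ID at or above the threshold passed 2-fold, 22 higher and 73 lower in Tc9 cells. The unchanged lists held random genes, so the 4% follows from the construction and does not cover lists of co-regulated genes.

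The alternatives were median centring, quantile normalization, a lowess correction on mean intensity (span 0.3), the mean of a gene's probe sets, other thresholds for detection (none, the 25th and the 75th percentile), other fold limits (1.5 and 3), a pseudocount of 16, and, for lists, detectable members only. Setting values below the threshold to it was added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.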

Results

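Gene expression was compared between Tc1 and Tc9 cells, which are CD8 T cells polarized in culture toward interferon gamma production and toward interleukin 9 production, respectively. The aim stated with the series was to find genes expressed more highly in Tc9 cells. CD8 T cells from mouse spleen and lymph nodes were activated through CD3 and CD28. They were polarized for 3 days and then kept for 2 more days in medium with 10 ng/mL IL-2. The Tc9 medium held 10 ng/mL IL-4, 1 ng/mL TGF-beta and 20 µg/mL of an antibody against interferon gamma, and the Tc1 medium held 10 ng/mL IL-2. IL-2 at 10 ng/mL is recorded for both groups, and whether the Tc9 polarizing medium also held it was not settled here. There was 1 array per group, so none of the differences below has a replicate check, and each describes this pair of arrays. Log2 gene signals on the arrays correlated across the 19505 genes with Pearson's r = 0.980, and genes are not independent replicates.

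The Tc9 array had far higher signals for Itgae, the alpha E integrin chain CD103, and for Ccr8, a chemokine receptor of type 2 and skin-homing T cells, than the Tc1 array. Itgae was at least 20.1-fold higher and Ccr8 at least 31.1-fold higher. Mmp12, a metalloprotease known as macrophage elastase, was 25.4-fold higher, at log2 signals of 6.49 on the Tc1 array and 11.16 on the Tc9 array. In the other direction, Selp, which encodes P-selectin, was 24.8-fold lower in Tc9 cells, and Serpinb9, an inhibitor of granzyme B, was 21.6-fold lower. Of 10147 detectable genes, 266 were at least 2-fold higher in Tc9 cells and 283 were at least 2-fold lower. Centring each array on its median shifted all differences by 0.11 on the log2 scale, and the counts became 329 and 229, a share of higher genes of 59.0% against 48.5%. On the array with the lower signal, 118 of the 266 and 107 of the 283 genes lay below the detection threshold, and with dim values set at the threshold 204 and 225 genes passed 2-fold.

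The 12 genes with the largest measured differences toward Tc9 cells also held Chil3 and Chil4, a pair of chitinase-like genes, at least 9.18-fold and at least 2.08-fold higher. Il24, a cytokine of the IL-10 family, was at least 11.8-fold higher, and Akr1c18, a hydroxysteroid dehydrogenase, at least 10.8-fold. Epas1, a hypoxia-inducible transcription factor subunit, was at least 8.39-fold higher. Efna5, an ephrin, was at least 7.20-fold higher, Trat1, an adaptor of the T cell receptor complex, at least 6.40-fold, Fgf2, a fibroblast growth factor, at least 5.76-fold, and Cask, a scaffold kinase, at least 4.68-fold. Of the 12 genes, Mmp12 alone reached the detection threshold on the Tc1 array, so dim values decide part of this set. With dim values at the threshold, 7 of the 12 stayed among the 12 largest differences, and Nt5e, Tmem176b, Emp1, Gpm6b and Aqp3 took the places of Chil4, Efna5, Trat1, Fgf2 and Cask. Monocyte and macrophage markers, of which 4 of 11 were detectable, had a median difference of 0.38 and of 0 with dim values at the threshold.

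The 12 genes with the largest measured differences toward Tc1 cells held 3 genes of the Ifi200 family, whose members interferons induce. These genes, Ifi211, Ifi213 and Ifi208, were at least 4.48-fold, 12.1-fold and 7.37-fold lower in Tc9 cells. Ly6c2 and Ly6c1, surface proteins of effector and memory CD8 T cells, were 14.5-fold and 12.2-fold lower. Ms4a4c, a membrane protein gene, was 19.2-fold lower. Gbp2, a guanylate-binding protein, was 12.7-fold lower, Xaf1 at least 6.27-fold, and Cxcl9, a chemokine induced by interferon gamma, at least 3.91-fold. Serpinb6b, another protease inhibitor, was 11.1-fold lower. With dim values at the threshold, 8 of these 12 stayed, and Iigp1, Ms4a4b, Plaur and Tbx21 took the places of Ifi211, Ifi208, Xaf1 and Cxcl9. The control probe sets give a scale for measured differences. Of the 585 controls with neg in their ID that reached the threshold, 16.2% differed by 2-fold or more, with log2 differences of all 585 between -2.42 and 1.61. They leaned toward lower signals in Tc9 cells, with 22 at least 2-fold higher and 73 at least 2-fold lower. Of 1158 controls with pos in their ID, 1.30% differed by 2-fold or more, against 5.41% of the genes. Controls and genes were not matched on intensity, so these shares are not a like comparison.

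**Figure D1:**
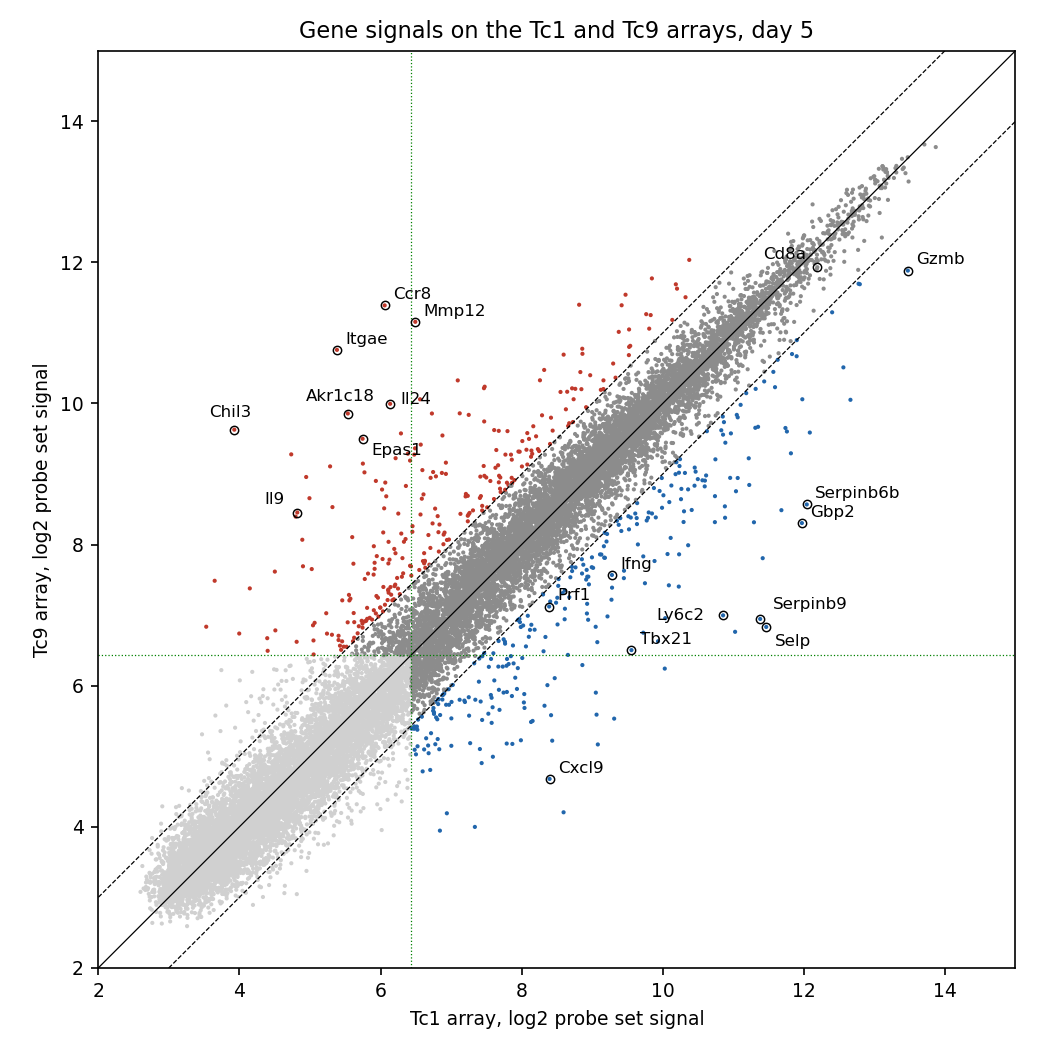
Log2 probe set signal of each of 19505 genes on the Tc1 array (x axis) and the Tc9 array (y axis), 1 array per group. Red and blue points are the 266 detectable genes at least 2-fold higher and the 283 at least 2-fold lower in Tc9 cells, dark grey points are other detectable genes, and light grey points lie below the detection threshold of 6.43 (dotted lines) on both arrays. The solid line marks equal signals, the dashed lines mark 2-fold differences, and circles mark the genes labelled by symbol. Itgae, Ccr8 and Mmp12 lie far above the dashed lines, and Selp and Serpinb9 far below.

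Il9 and the type 1 genes Ifng, Tbx21 and Eomes differed in the directions the culture labels name. In the Tc9 and Th9 identity list, Spi1 went the other way and Irf4 hardly differed. Il9 was at least 4.07-fold higher in Tc9 cells, with a log2 signal of 4.82 on the Tc1 array and 8.45 on the Tc9 array. Ifng, the signature cytokine of Tc1 cells, was 3.27-fold lower, at 9.28 and 7.57. Tbx21, the T-bet transcription factor of the type 1 program, was 8.30-fold lower, and Eomes, its relative, was 2.09-fold lower, which fell under 2-fold when the arrays were median centred. Cd8a differed by 1.20-fold. Of 11 measured genes of the Tc9 and Th9 identity list, 3 were at least 2-fold higher in Tc9 cells and none was as much lower. Besides Il9 these were Il17rb, the IL-25 receptor, at least 1.18-fold, and Batf, a transcription factor, 2.43-fold. Irf4 differed by 1.03-fold. Spi1, which encodes PU.1, was 1.60-fold lower in Tc9 cells. B cells express Spi1 as well, and the B cell markers had a median difference of -0.43. The list's median difference was 0.36, above those of all but 16 of 10000 matched random lists, and 0.24 with dim values at the threshold. Gata3 and Il1rl1 were not analysed here.

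Genes of the type 1 program were lower in Tc9 cells for 8 of 20 measured members at 2-fold or more, and higher for 1. Ccl5, an effector T cell chemokine, was 7.85-fold lower, Il12rb2, the signalling chain of the IL-12 receptor, 6.10-fold lower, and Ccl3, another chemokine, 4.91-fold lower. Id2, a transcriptional regulator of effector cells, was the member that was higher, 2.27-fold. The median difference was -0.66, below each of the 10000 random lists, and -0.96 over the 16 detectable members. Of 21 measured cytotoxic granule genes, 7 were at least 2-fold lower and 1 was higher. Gzmb was 3.01-fold lower, at log2 signals of 13.47 and 11.88, Prf1, which encodes perforin, 2.41-fold lower, and Gzmc at least 4.01-fold lower. Serpinb9 and Serpinb6b, which inhibit proteases rather than kill, were 2 of the 7. Tnfsf10, the death ligand TRAIL, was 4.46-fold higher in Tc9 cells. The median of this list was -0.57 over all members but 0.10 over the 16 detectable ones and 0 with dim values at the threshold, with a mean of -0.71 over all. Of 14 NK receptor genes, 4 were at least 2-fold lower and none higher, with a median of -0.72. Klrk1, the activating receptor NKG2D, was at least 3.26-fold lower, Klrd1 at least 2.74-fold and Fcer1g, a signalling adaptor, 3.18-fold. The last of the 4, Klrb1c, was below the threshold on both arrays. Only 4 members of that list were detectable, with a median of -1.62 over these, and with dim values at the threshold its median was 0.

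Type 2 and IL-4 response genes were higher in Tc9 cells as a group. Of 19 measured members, 9 were at least 2-fold higher and none was 2-fold lower. Ccl24, an eotaxin, was at least 6.03-fold higher and Il10 at least 1.93-fold, beside Ccr8 and Il24 above. Of the classical type 2 cytokines, Il4, counted among the 9, and Il5 were below the threshold on both arrays, and Il13, just above it, had a log2 difference of 0.01. The list's median difference was 0.91, above each of the 10000 random lists, 1.67 over the 13 detectable members and 0.24 with dim values set at the threshold. Of 17 measured TGF-beta and SMAD response genes, 5 were at least 2-fold higher and none lower, with a median of 0.65, above each random list. After Itgae, the largest were Ldlrad4, an inhibitor of TGF-beta signalling, at least 3.11-fold, Tgfbr1, the type I TGF-beta receptor, 4.71-fold, and Cdh1, which encodes E-cadherin, the ligand of CD103, 4.29-fold. The remaining gene, Tgfb3, was at least 2.21-fold higher. Among 17 chemokine receptors, 5 were at least 2-fold higher and 2 lower in Tc9 cells. Cxcr6 was at least 3.91-fold and Ccr4 4.20-fold higher, and Ccr7, the lymph node homing receptor, was 2.16-fold lower. Ccr9 and Cx3cr1, counted as higher, and Ccr2, counted as lower, were below the threshold on both arrays. Their median was 0.54, with 0.96 over the 7 detectable ones and 0 with dim values at the threshold.

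Interferon-inducible genes formed the lists with the most negative medians. Of 19 measured interferon gamma target genes, 15 were at least 2-fold lower in Tc9 cells and none was 2-fold higher. Iigp1, an immunity-related GTPase, was 9.88-fold lower and Gbp7 7.87-fold lower. The median difference was -1.86, where the central 95% of random lists ran from -0.11 to 0.19. Of 21 measured type I interferon-stimulated genes, 16 were at least 2-fold lower and none higher, with a median of -1.68, and 2 of the 16, Mx1 and Rtp4, were below the threshold on both arrays. Oas3 and Oasl2, of the oligoadenylate synthetase family, were at least 3.96-fold and 2.95-fold lower, and Ifit1 at least 1.33-fold lower. With dim values set at the threshold the medians were -1.58 and -1.16.

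**Figure D2:**
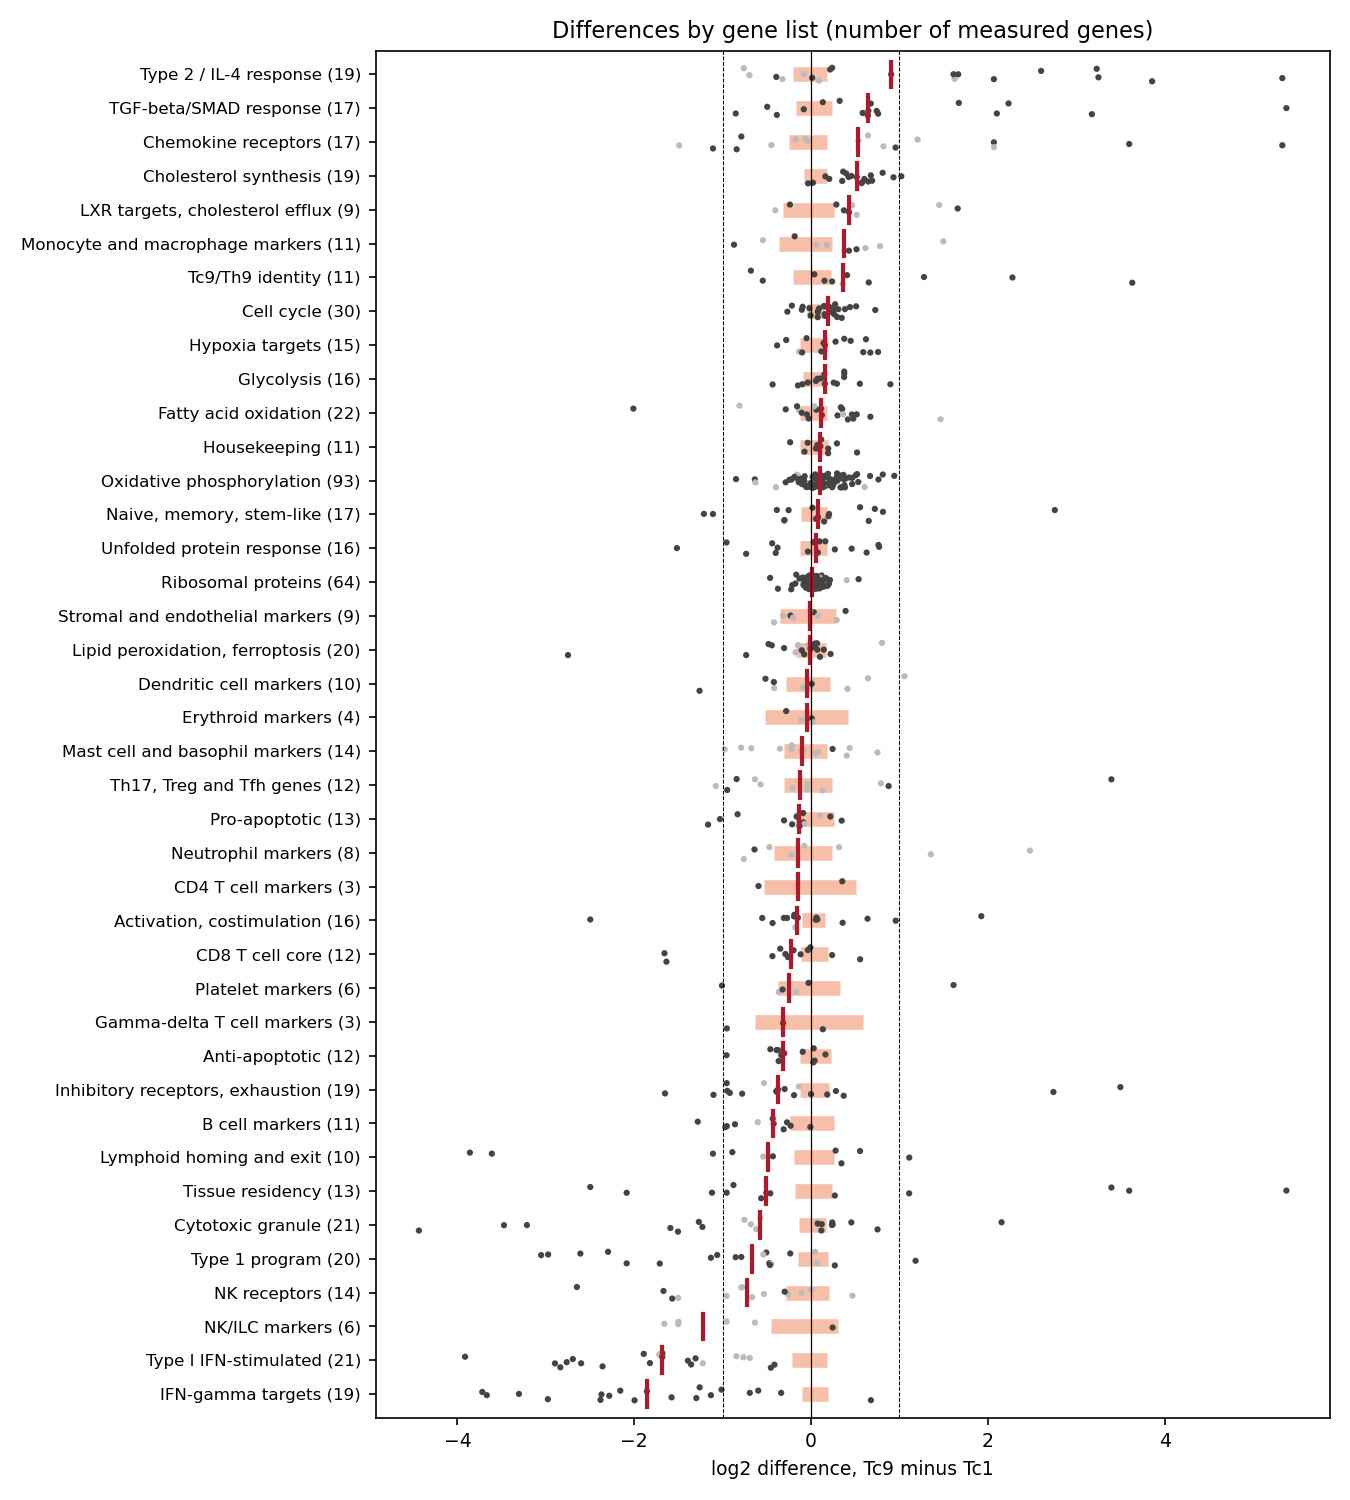
Log2 difference, Tc9 minus Tc1 (x axis), for the measured genes of the 40 gene lists (rows, with the number of measured genes). Each dot is a gene, dark where it was detectable and light where both arrays were below the threshold, the red tick is the list's median, and the orange band is the central 95% of the medians of 10000 random lists matched on mean expression. The dashed lines mark 2-fold. The type 2 and IL-4 response list has the highest median, 0.91, and the interferon gamma target list the lowest, -1.86.

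Genes of tissue residency differed in both directions. Of 13 measured members, 4 were at least 2-fold higher in Tc9 cells and 3 lower, with a median of -0.51 but a mean of 0.36. Beside Itgae and Cxcr6, Ahr, the aryl hydrocarbon receptor, was at least 6.57-fold higher, and Cd101 at least 1.60-fold, while Cd69, an early activation marker that retains T cells in tissue, was 5.65-fold lower, Rgs1 2.17-fold and Prdm1, the Blimp-1 transcription factor, at least 1.79-fold. Of 10 genes of lymphoid homing and exit, 3 were lower, Ly6c1, Ly6c2 and Ccr7, and S1pr1, the receptor that guides exit from lymph nodes, was 2.16-fold higher, with a median of -0.49, and -0.22 with dim values at the threshold. Naive, memory and stem-like genes had a median of 0.08 over 17 members, inside the random range, with Il6ra, an IL-6 receptor chain, at least 5.10-fold higher and Dapl1 and Ccr7 2.32-fold and 2.16-fold lower. Tcf7 was not analysed here. Of 19 inhibitory receptor and exhaustion genes, 2 were higher and 2 lower, with a median of -0.37, below each of 10000 random lists, and a mean of -0.08. Nt5e, the ectoenzyme CD73, was 11.3-fold higher and Cd200r1 at least 1.24-fold, and the orphan nuclear receptors Nr4a2 and Nr4a3 were 3.14-fold and 2.15-fold lower, the latter falling under 2-fold after median centring. The differences of Pdcd1, Lag3, Tigit and Ctla4 lay between -0.39 and 0.37, and Havcr2 was below the threshold on both arrays. Among 16 activation and costimulation genes, Egr2 was 3.80-fold higher and Cd69 lower, and the median was -0.16, and -0.07 with dim values at the threshold. A median as low as -0.16 occurred in 45 of 10000 random lists. The Th17, Treg and Tfh list had a median of -0.13 over 12 members, inside the random range, a mean of 0.07, and a median of 0 with dim values at the threshold. It had Ahr as its only member at least 2-fold higher and Il17a, below the threshold on both arrays, as its only member 2-fold lower.

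None of 30 cell cycle genes differed by 2-fold, and their median was 0.20, at percentile 99.8 of the random lists. Genes of cholesterol synthesis were slightly higher in Tc9 cells as a group, with 18 of 19 members within 2-fold and a median of 0.52, above each of the 10000 random lists. Pmvk, phosphomevalonate kinase, was 2.03-fold higher, a difference that fell under 2-fold after quantile normalization, Hsd17b7 was 1.91-fold and Dhcr7 1.75-fold higher. Of 9 LXR target and cholesterol efflux genes, 2 were at least 2-fold higher, with a median of 0.43, and 0 with dim values at the threshold. Scd1, a fatty acid desaturase, was 3.16-fold higher, and the other, Abca1, was below the threshold on both arrays. Medians were 0.12, and 0.03 with dim values at the threshold, for 22 fatty acid oxidation genes, -0.02 for 20 genes of lipid peroxidation and ferroptosis, 0.15 for 16 glycolysis genes, 0.10 for 93 genes of oxidative phosphorylation, 0.02 for 64 ribosomal protein genes, 0.05, with a mean of -0.07, for 16 genes of the unfolded protein response and 0.16 for 15 HIF target genes. In these lists the genes at least 2-fold lower were Acsl6, an acyl-CoA synthetase, at least 2.70-fold, Ptgs2, a prostaglandin synthase, at least 1.42-fold, and Atf3, a stress transcription factor, 2.86-fold. Cd36, a fatty acid transporter, was the only member 2-fold higher and was below the threshold on both arrays. None of 12 anti-apoptotic genes differed by 2-fold, with a median of -0.32, and 3 of 10000 random lists had a median as low. Of 13 pro-apoptotic genes, 2 were lower, Bcl2l11, which encodes BIM, 2.24-fold and Fas 2.04-fold, the latter under 2-fold after median centring, and the median was -0.13.

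Markers of T cells and of other cell types were read in the same way. The 12 measured CD8 T cell core genes had a median of -0.23, and 13 of 10000 random lists had a median as low. The surface receptors Cd5 and Cd6, 2 of these genes, were 3.15-fold and 3.11-fold lower in Tc9 cells. The 11 housekeeping genes had a median of 0.11. Several B cell markers were well above the threshold on both arrays, with Cd79a, a chain of the B cell receptor, at log2 signals of 10.65 and 9.68. All 11 measured markers had lower signals in Tc9 cells, except that Ebf1, at -0.01, turned after median centring. Their median of -0.43 was matched or passed by 5 of 10000 random lists, and 10 of the 11 differed by less than 2-fold, Fcrla being lower by at least 1.30-fold. Of 11 monocyte and macrophage markers, 4 were detectable, among them Lyz2 at 8.36 and 8.79 and Fcgr3 at 8.41 and 7.54. The median of all 11 was 0.38, matched or passed by 21 of 10000 random lists. None of the detectable ones differed by 2-fold, and Mrc1, the member past 2-fold, was below the threshold on both arrays. The dendritic cell list had a median of -0.05 over 10 genes and -0.47 over the 4 detectable ones, with H2-Aa, a class II molecule that B cells also express, at 11.10 and 10.68. Zbtb46 was at least 1.33-fold lower, and Itgax, counted as higher, was below the threshold on both arrays. NK and innate lymphoid markers had a median of -1.23 over 6 genes, of which only Kit, also a mast cell marker, was detectable. The 3 members past 2-fold, Klrb1c, Klrb1b and Klri2, were below the threshold on both arrays. Neutrophil markers, of which 1 was detectable, had a median of -0.15 and a mean of 0.25 over 8 genes, and the members past 2-fold, S100a8 and S100a9, were below the threshold on both arrays. Medians were -0.10 for 14 mast cell and basophil, -0.15 for 3 CD4 T cell, -0.32 for 3 gamma-delta T cell, -0.05 for 4 erythroid, -0.25 for 6 platelet and -0.01 for 9 stromal and endothelial markers. Itgb3, an integrin of platelets and activated T cells, was 3.06-fold higher in Tc9 cells, Itga2b was at least 1.27-fold lower, and Pf4, a platelet chemokine, differed by 1.02-fold. With dim values at the threshold, the medians were -0.37 for B cell, -0.06 for gamma-delta T cell and -0.01 for platelet markers, and 0 for each of the other lists of markers of cells other than CD8 T cells.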

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

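No paired analysis was possible because each group has 1 array, and no array could be left out. Among these values, the alternative that sets dim values to the threshold was chosen only after the data were seen. The counts of genes at least 2-fold higher and lower in Tc9 cells, 266 and 283, stayed within 1.5 times of these under median centring (329 and 229), quantile normalization (263 and 278), the lowess correction (263 and 285), the mean of a gene's probe sets, a pseudocount of 16 (218 and 244), and detection thresholds at the 25th percentile (344 and 395) or absent (352 and 405). Quantile normalization kept 251 of the 266 and 261 of the 283 genes. The counts were 123 and 144 at the 75th percentile, 791 and 688 at 1.5-fold, and 110 and 118 at 3-fold, which by construction test fewer genes or another limit. With dim values at the threshold they were 204 and 225. Over detectable members only, which leaves fewer genes by construction, the medians became 0.10 for cytotoxic granule genes, turned from -0.57, and 0.24 for NK and innate lymphoid markers, turned from -1.23 with 1 gene left. They moved further from 0 for the type 1 program (-0.96), type 2 and IL-4 response genes (1.67), NK receptors (-1.62), chemokine receptors (0.96), dendritic cell markers (-0.47) and neutrophil markers (-0.64, 1 gene left). The median of mast cell and basophil markers, -0.10, became 0.24 with Kit as the 1 gene left. With dim values at the threshold, the medians were 0 for cytotoxic granule genes, NK receptors, chemokine receptors, LXR targets, the Th17, Treg and Tfh list, ferroptosis genes, and markers of macrophages, NK and innate lymphoid cells, CD4 T cells, neutrophils, dendritic, mast, erythroid and stromal cells, -0.22 for lymphoid homing and exit, 0.24 for both type 2 and IL-4 response genes and Tc9 identity genes, -1.58 for interferon gamma targets, and -1.16 for type I interferon-stimulated genes, since dim genes keep only a lower bound of their difference. Likewise they were -0.65 for the type 1 program, 0.64 for TGF-beta response, -0.30 for inhibitory receptor, -0.07 for activation, 0.03 for fatty acid oxidation and 0.0028 for ribosomal protein genes, and -0.37 for B cell, -0.06 for gamma-delta T cell and -0.01 for platelet markers. The other 12 list medians were the same at 2 decimals. Median centring moved the medians to 0.31 for cell cycle, 0.21 for oxidative phosphorylation and 0.12 for ribosomal protein genes. Of the 12 genes with the largest measured differences in each direction, 7 higher and 8 lower ones stayed with dim values at the threshold. Of 40 list medians, 22 lay outside the central 95% of random lists, and 0 of these changed sign under the 3 scalings or the mean of probe sets. Of the 18 inside it, 6 did, for dendritic cell, erythroid, mast cell and stromal markers, ferroptosis and unfolded protein response genes. Of 76 named genes at least 2-fold apart, 5 came under 2-fold in at least 1 of those 4 alternatives, Eomes, Fas, Itga2b, Nr4a3 and Pmvk. That count leaves out dim values at the threshold. With these, further named genes came under 2-fold, among them Il17rb, Cd200r1, Fcrla, Ifit1, Zbtb46, Ptgs2 and Il10. The 3 probe sets of Egr3 ran from -0.03 to 0.96, and averaging them moved its difference from 0.96 to 0.54. Of the 19505 genes, 10147 reached the detection threshold, and for the others signal over background limits what can be seen.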

Other observations

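The tests below that were chosen only after the result was seen are those on macrophage share, probe noise, scaling, B cell share behind the interferon genes, and interferon type. Those on the further IL-4 macrophage, B cell, retinoid and AHR genes were written before the values they used were seen.

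Genes were also grouped by the stem of their symbol, a grouping chosen after the data were seen, which gave 244 families with at least 6 detectable members. Some members, such as Gbp2, Gbp7, Serpinb9, Serpinb6b and Tnfsf10, are also in the lists above, so their values are not new. The Gbp family, interferon-inducible GTPases, was lower in Tc9 cells in all 6 detectable members, from Gbp2 at -3.67 to Gbp8 at -1.52 on the log2 scale, with a median of -2.29. Of 6 detectable Serpinb genes, intracellular protease inhibitors, 5 were at least 2-fold lower, with a median of -1.88. Serpinb6a was the exception at -0.37. Of 10 detectable Ifi genes, 8 were at least 2-fold lower, with a median of -2.07. The Tnfsf family of TNF-like ligands had the highest median, 0.63 over 7 genes. Tnfsf10 was 4.46-fold higher in Tc9 cells, Tnfsf11, which encodes RANKL, 2.15-fold, and Tnfsf13b, which encodes BAFF, at least 2.92-fold, while Tnfsf8 was lower at -0.74 and Tnfsf4 at -0.59. Members of a family can share probes.

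Among 1091 probe sets at or above the threshold that carry no gene symbol here and belong to no named control set, 27 were at least 2-fold higher and 59 at least 2-fold lower in Tc9 cells. The Y-linked genes Uty and Eif2s3y differed between the arrays by -0.07 and -0.06.

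A first pattern is that 5 genes known from IL-4-activated macrophages, Chil3, Mmp12, Arg1, Ccl24 and Chil4, were higher in Tc9 cells by log2 differences of 1.06 to 4.66 with dim values at the threshold, Ccl24 being also in the type 2 list. Probe noise is argued against for Mmp12, at 4.66, Chil3, at 3.20, and Ccl24, at 2.59. The largest such difference toward Tc9 among 585 control probe sets at or above the threshold was 1.28. Toward Tc1, these controls reached -2.42 as measured, and the genes were picked from 10147 detectable ones, so the margin for Ccl24 is small. Noise stays open for Arg1, at 1.22, and Chil4, at 1.06, since 6 of these controls differed by as much as Chil4. A larger share of macrophages left after the CD8 isolation stays open, since the upper quartile of the 11 monocyte and macrophage markers was 0.57, but only 4 of them reached the threshold, Lyz2 at log2 signals of 8.36 and 8.79 and Fcgr3 at 8.41 and 7.54 being the brightest. IL-4 acting on macrophages present in both cultures stays open too, since of 4 further detectable genes induced by IL-4 in macrophages 25% was 2-fold higher as measured, Fn1, at least 1.81-fold against its dim Tc1 value, with Il1rn at 0.82, Tmem26 at 0.32 and Clec10a at -0.10. Expression by the Tc9 cells themselves, the difference the design names, was not tested apart from these explanations.

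A second pattern is the low signal of interferon-inducible genes in Tc9 cells. Array scaling is argued against by its size. Median centring shifted all differences by 0.11, and under the 3 planned scalings the medians of both interferon lists stayed at -1.57 or below. The arrays were already close in scale, so these scalings could move the medians only little. A smaller share of B cells as the whole cause is argued against as well, because the lower quartile of the B cell marker differences was -0.91, above the list medians of -1.86 and -1.68. Whether neutralised interferon gamma alone could account for the pattern cannot be told apart from less type I interferon signalling. The interferon gamma list's median minus that of the type I list was -0.17, and many genes respond to both interferons. The antibody, IL-4 and TGF-beta were all in the Tc9 medium, so the design does not separate them. Nor does it separate them from any difference in IL-2 between the polarizing media.

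The third pattern is that Spi1, a factor known for IL-9 production in T helper cells, was lower in Tc9 cells, with a log2 difference of -0.68. Several B cell genes were bright on both arrays, Cd79a at 10.65 and 9.68, and less B cell RNA in the Tc9 culture may contribute. Of 12 further detectable B cell genes 66.7% were lower in Tc9 cells, with a median of -0.34, short of the 75% set in advance. Of the 11 B cell markers fixed earlier, all were lower, Ebf1 at -0.01 turning after median centring, and 5 of 10000 random lists had a median as low as their -0.43. The share of the Spi1 signal that comes from B cells was not measured.

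The retinoid genes Stra6, Crabp2 and Rxra were 6.01-fold, 6.78-fold and at least 5.28-fold higher in Tc9 cells, which raised the hypothesis of retinoic acid signalling. Of 5 further detectable retinoid genes 40% were 2-fold higher as measured, Rara at 2.56-fold and Dhrs3 at least 1.42-fold, while Hic1 was at 0.91, Tgm2 at -0.26 and Rarg at -0.38 on the log2 scale. The median of all 13 measured members was 0.03, inside the random range, and 0 with dim values at the threshold, and the hypothesis stays open. For AHR signalling, given the higher Ahr, only 2 of 6 target genes were detectable. Of these 50% was 2-fold higher as measured, Tiparp, at least 1.54-fold, beside Ahrr, at least 1.94-fold, and 2 genes are too few to decide. Epas1 was higher by at least 8.39-fold, while none of the 15 HIF target genes fixed in advance differed by 2-fold.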
